A study of Williopsis jadinii with 2 samples.

How the data were processed

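RNA was sequenced from the wild-type yeast strain NBRC0988 of Cyberlindnera jadinii, a food and fodder yeast that was long known as Candida utilis. Per the labels' protocols, cells were grown for 15 h in a glucose medium from an OD600 of 0.1 to an OD600 of 2 to 3, washed, and moved for 5 h at 30 °C and 250 rpm into fresh rich medium with 2% (w/v) glucose or 2% (w/v) xylose. RNA was extracted with Trizol, treated with DNase I on a column, and made into strand-specific paired-end libraries with reads of 150 nt. There was 1 library per sugar.

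The authors deposited, for each library, a table of 5880 genes with the coding length, a raw read count and an FPKM value. The read counts are whole numbers that were not normalised, per the file headers, and they sum to a different total in each library. The submitters' processing notes name the aligner HISAT2 (version 2.2.1). The counting tool, its strand setting, the treatment of reads that map to several places, the genome build and the gene annotation are not given in the sources used here. Values of overlapping, antisense or near-identical genes may therefore share reads. The FPKM values deposited by the authors followed from the counts: each equalled the count divided by the coding length in kilobases and by the column total per 1000000 counts, within a relative tolerance of 1e-06, and 0 values lay beyond it. They hold no further information and were not tested. The deposited coding lengths ran from 201 to 14664 bases, and all 5880 were multiples of 3, so they hold no UTRs.

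The files identify genes only by running IDs that begin with CJ. None of these IDs occurs in the RefSeq gene table of the species that was at hand (0 matches among 6184 genes, made from another strain), and the files pair no ID with a gene name or product. The 25 lists of pathways and complexes that had been fixed before the data were examined, among them the xylose entry enzymes, the pentose phosphate pathway, glycolysis, respiration, sugar transporters and ribosomal proteins, could therefore not be matched to any gene, and no result is given for them. Genes were grouped by expression level, by coding length and by size of difference in their place. The rule for naming genes, fixed before the data were examined, was in this case the 2 IDs with the highest and the 2 with the lowest log2 ratio, which includes the pseudocount of 1 described below, among genes past the count minimum. By the ratio without a pseudocount, 1 other gene would rank above the second of the higher IDs and 3 other genes below the second of the lower IDs. Each of these has at most 2 counts in the library with the lower level. The 2 genes with the largest shares of the counts were named in addition, after their values were seen.

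Library sizes were scaled with the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3. The TMM factor was 1.10 for glucose and 0.91 for xylose. CPM values (counts per 1000000 of the library size) were computed on the scaled sizes, and the log2 ratio was taken as log2 of (xylose CPM + 1) over (glucose CPM + 1), which understates the difference of genes with few counts. Folds given for single genes carry no pseudocount, and their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the counts. Classes such as at least 2-fold or at least 4-fold use the log2 ratio with the pseudocount, which leaves out some genes with few counts. Genes with at least 50 counts over both libraries were compared (5643 genes). The other 237 genes held 0.0122% of all counts. A gene was counted as higher or lower when its log2 ratio reached 1 in size, a 2-fold difference, and its interval excluded equality.

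With 1 library per sugar there is no estimate of the spread between cultures, so no p-value was computed and every comparison is between these 2 libraries. The intervals cover counting error only, and reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, or 0.185 CPM in the glucose library and 0.252 CPM in the xylose library. The procedure was tested on simulated data for the 5880 genes, drawn with Poisson error from the mean profile of the 2 libraries. Of the simulated genes changed 3-fold, 4-fold or 8-fold, 100% were called in each class and direction, and 0 of 5440 unchanged genes were called. The interval covered equality for 95.1% of the unchanged genes. These simulated libraries hold counting error and no variation between cultures. Their changes were balanced between the directions and at least 3-fold, so scaling under uneven differences and calls near 2-fold were not tested.

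Alternatives fixed before the data were examined were scaling by total counts, the median-of-ratios size factors of DESeq2 1.42.0, no count minimum (every gene with a count), a minimum of 500 counts, pseudocounts of 5 and 0.1, removal of the 20 most abundant genes of either library before scaling (31 genes), and a 4-fold threshold. Upper-quartile scaling, and the 4-fold threshold together with total-count scaling or with 500 counts, were added after the data were seen.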

Results

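The series addressed how gene expression of C. jadinii differs between growth on glucose, the preferred sugar of most yeasts, and growth on xylose, a pentose of plant biomass. It holds 1 glucose library and 1 xylose library, without replicates. The glucose library had 14728899 counts and the xylose library 13061052 counts over the same 5880 genes. At least 10 counts were found for 5723 genes (97.3%) in glucose and for 5654 genes (96.2%) in xylose. The median gene had 906 counts in glucose and 679 in xylose. No count was found for 44 genes in either library, for 20 genes in glucose alone and for 47 genes in xylose alone.

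The transcript pool was divided differently among the genes in the 2 libraries. Of all counts, 25.5% would have to be moved between genes to turn one library's profile into that of the other. The genes with a larger share of counts in xylose numbered 2129, and 83 of them made up 50% of the gain. The genes with a smaller share numbered 3707, and 110 of them made up 50% of the loss. These shares are of each library's total counts, so the split into larger and smaller shares is that of total-count scaling. The median log2 ratio of the compared genes was -0.27 with total-count scaling and -0.01 with TMM scaling. Across the 5643 genes with at least 50 counts, log2 CPM in xylose and glucose had a Pearson correlation of 0.831 and a Spearman correlation of 0.842. Both describe genes within these 2 libraries, and genes are not independent replicates.

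The 2 genes with the most counts were the same in both media. Abundance ranks throughout are by counts, not divided by coding length, so the order by transcript number can differ. CJ2232 (coding length 1620 bases) ranked 1 in each library, with 2.46% of the glucose counts (95% Clopper-Pearson interval 2.46% to 2.47%) and 2.22% of the xylose counts (2.21% to 2.22%). CJ0102 (1005 bases) ranked 2 in each, with 2.46% of the counts in glucose and 2.15% in xylose. Their log2 ratios were 0.12 and 0.08 with TMM scaling, and -0.15 and -0.19 with total-count scaling, so their direction depended on the scaling. The 10 most abundant genes held 12.7% of the glucose counts and 11.3% of the xylose counts. The 100 most abundant held 35.2% and 34.2%. Of the top 100 genes of each library, 64 were shared. Among the top 100 of xylose, 36 genes were at least 2-fold higher there than in glucose and 22 were at least 4-fold higher. Among the top 100 of glucose, 23 were at least 2-fold lower in xylose and 11 were at least 4-fold lower.

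In xylose, 868 genes (15.4% of those compared) were at least 2-fold higher than in glucose, and 492 genes (8.72%) were at least 2-fold lower. The other 4283 genes (75.9%) were in neither group. The genes at least 2-fold higher took 7.53% of the counts in glucose and 27.3% in xylose. The genes at least 2-fold lower took 13.5% in glucose and 2.70% in xylose. Higher genes made up 63.8% of the genes at least 2-fold apart (95% Clopper-Pearson interval 61.2% to 66.4%), but 44.8% (42.2% to 47.4%) when the libraries were scaled by total counts, which gave 660 higher and 814 lower genes. Total-count scaling moved the median log2 ratio of the compared genes from -0.01 to -0.27, so which direction held more genes at 2-fold depended on the scaling. No test between the sugars was possible with 1 library each, and variation between cultures was not measured.

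**Figure D1:**
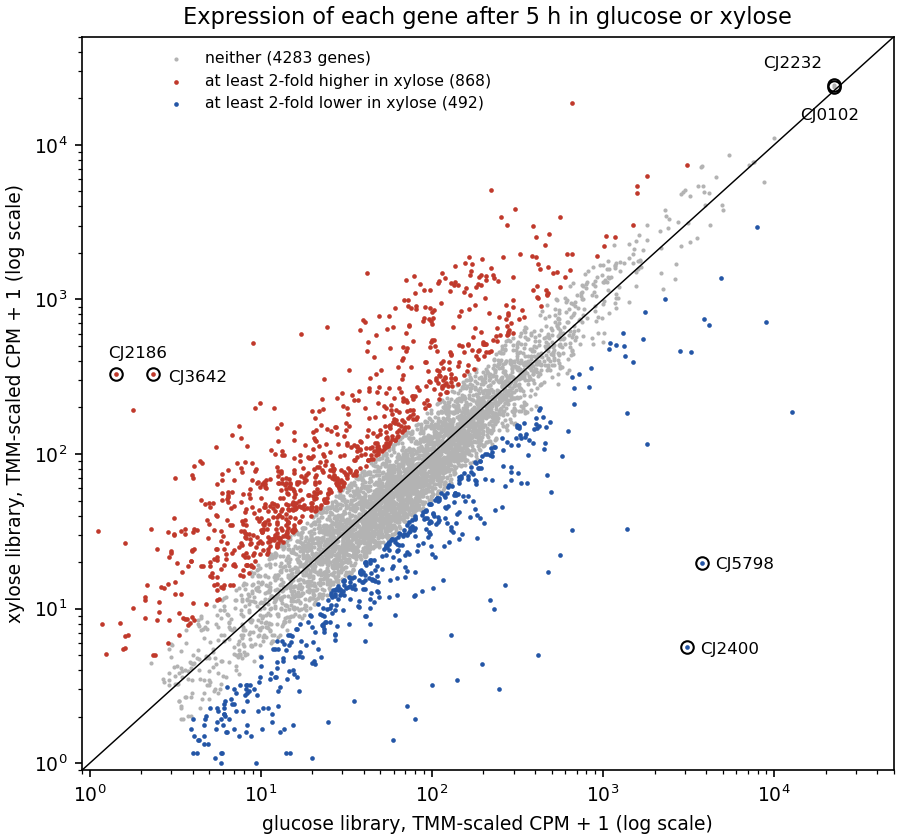
Each point is 1 of 5643 genes with at least 50 counts, placed by its TMM-scaled CPM plus 1 in the glucose library (x, log scale) and in the xylose library (y, log scale). The line marks equality, the 868 red genes lie at least 2-fold above it and the 492 blue genes at least 2-fold below it, and circles mark the 6 genes named in the text.

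Larger differences were mostly towards higher expression in xylose up to a point. At least 4-fold differences were seen for 345 higher and 107 lower genes, or 76.3% higher (72.1% to 80.2%). With total-count scaling there were 284 higher and 142 lower genes, or 66.7% higher (62.0% to 71.1%). The 345 genes held 2.12% of the counts in glucose and 15.4% in xylose, and their median level was 15.9 CPM in glucose and 114 CPM in xylose. The 107 genes held 6.52% of the counts in glucose and 0.479% in xylose, with median levels of 78.7 CPM and 8.92 CPM. At least 8-fold differences were seen for 127 higher and 31 lower genes. At 16-fold the numbers were 29 and 20, and total-count scaling turned them to 19 and 22. At 32-fold, 6 genes were higher and 10 lower. These counts depended on the pseudocount, which was varied for them after the data were seen. With a pseudocount of 0.1 there were 377 higher and 141 lower genes at 4-fold, 149 and 48 at 8-fold, 33 and 32 at 16-fold, and 8 and 17 at 32-fold. With a pseudocount of 5 there were 266 and 58, 82 and 22, 13 and 12, and 5 and 6 at the same thresholds.

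**Figure D2:**
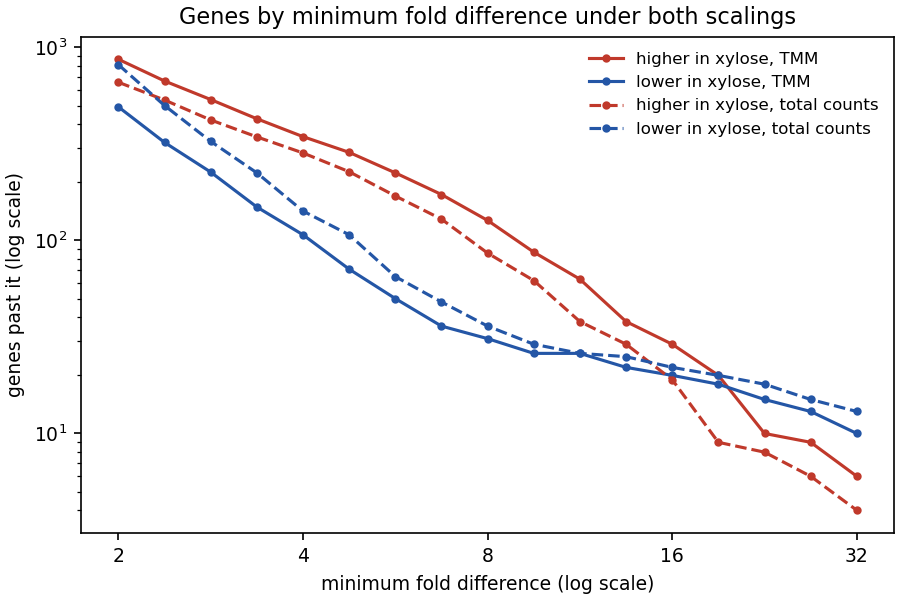
Number of genes (y, log scale) at or past each minimum fold difference (x, log scale), for genes higher (red) and lower (blue) in xylose, with TMM scaling (solid) and total-count scaling (dashed). Higher genes outnumber lower genes at 4-fold under both scalings, with 345 against 107 and 284 against 142, while at 2-fold the order differs between the scalings.

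The 4 genes with the most extreme log2 ratios, which include the pseudocount of 1, lay far from equality. CJ2186 (1434 bases) had 7 counts in glucose and 3877 in xylose, or 0.433 and 326 CPM, which is 754-fold higher in xylose (95% interval 366-fold to 1876-fold). It ranked 5735 of 5880 in glucose and 629 in xylose. CJ3642, with a short coding length of 234 bases, had 22 and 3932 counts and was 243-fold higher in xylose (160-fold to 389-fold). In the other direction, CJ2400 (1110 bases) ranked 32 in glucose with 50178 counts, or 3101 CPM, and ranked 5431 in xylose with 55 counts, or 4.63 CPM. It was 670.3-fold lower in xylose (515-fold to 890-fold by counting error). CJ5798 (1587 bases) ranked 24 in glucose with 61473 counts and 4711 in xylose with 222 counts, and was 203-fold lower (178-fold to 233-fold). The log2 ratios of these 4 genes were 7.84, 7.14, -9.11 and -7.59 in the order named. Below 1 CPM of the deposited total were 10 of the 345 genes in glucose and 22 of the 107 genes in xylose.

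Differences were spread unevenly over expression levels. The intervals given for shares of genes treat genes as independent, which they are not. The median gene had 442 counts over both libraries in the lowest quartile and 7473 in the highest. Counting error therefore weighs more in the lowest. In the quartile of compared genes with the lowest mean expression, 125 of 1411 genes (8.86%) were at least 4-fold higher in xylose and 52 (3.69%) at least 4-fold lower. The third quartile had the fewest, with 38 higher (2.70%) and 16 lower (1.13%). In the quartile with the highest expression, 109 genes (7.73%, 95% interval 6.39% to 9.24%) were at least 4-fold higher and 20 (1.42%, 0.868% to 2.18%) at least 4-fold lower. This quartile also had a median log2 ratio of 0.13, against -0.02 in the lowest quartile, and with total-count scaling these medians were -0.14 and -0.27. With total-count scaling the shares at least 4-fold higher were 7.09% in the lowest and 7.09% in the highest quartile, and the third quartile held 31 such genes.

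The share of higher genes by coding length depended on the threshold. At least 2-fold higher in xylose were 238 genes (16.8%) of the shortest quartile and 232 genes (16.5%) of the longest. Among the shortest quartile, with up to 768 bases, 116 of 1415 genes (8.20%, 6.82% to 9.75%) were at least 4-fold higher in xylose, against 72 of 1409 genes (5.11%, 4.02% to 6.39%) of the longest quartile. With total-count scaling the shares were 7.70% and 3.97%. At least 2-fold lower were 11.0% (9.46% to 12.8%) and 12.3% (10.6% to 14.1%) of the genes in the second and the third quartile, and 5.51% (4.38% to 6.83%) and 6.03% (4.85% to 7.41%) in the shortest and the longest. The median log2 ratios of these quartiles were -0.11, -0.07, 0.06 and 0.09 in the same order. With total-count scaling these 4 shares were 17.9%, 18.8%, 9.68% and 11.4%, and the medians -0.38, -0.34, -0.21 and -0.17. The median coding length was 1056 bases for the genes at least 4-fold higher, 1329 bases for those at least 4-fold lower and 1218 bases for all genes compared.

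**Figure D3:**
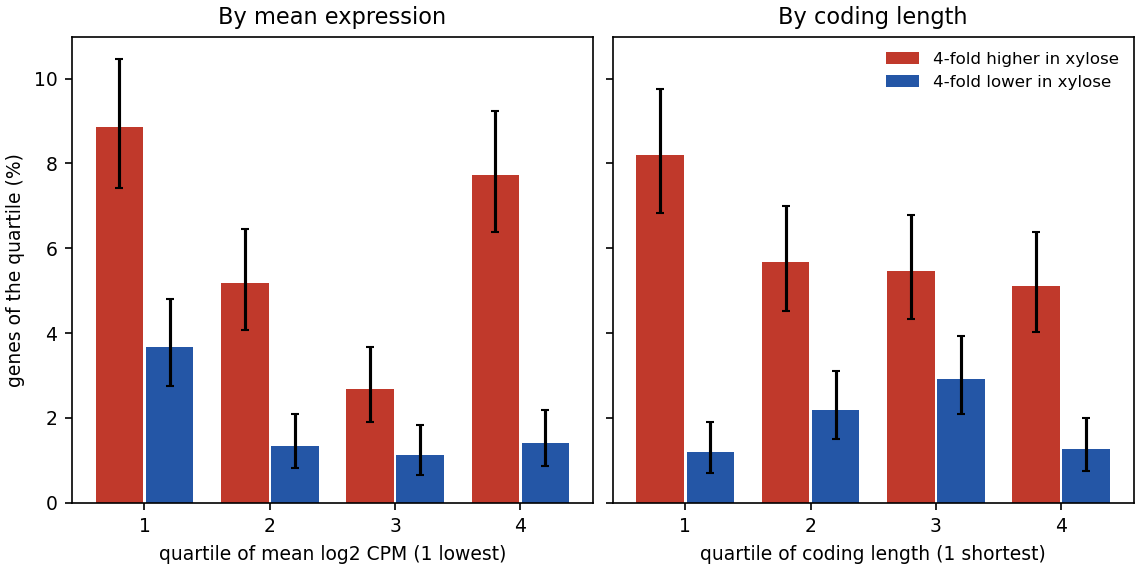
Share of genes at least 4-fold higher (red) or lower (blue) in the xylose library, as percent of each quartile of mean expression (left) and of coding length (right), with TMM scaling. Error bars are 95% Clopper-Pearson intervals over genes, and the bars for higher genes are tallest in the lowest expression quartile (8.86%) and in the shortest length quartile (8.20%).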

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

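Upper-quartile scaling and the 4-fold counts under total-count scaling or with at least 500 counts were chosen after the data were seen. Of all alternatives run, total-count scaling was the 1 that turned a direction: higher genes made up 44.8% of those at least 2-fold apart, with 660 higher and 814 lower genes. All 660 were among the 868 and all 492 lower genes were among the 814, and the shift of the median log2 ratio to -0.27 accounts for the difference by construction. The share of higher genes was 57.7% with upper-quartile scaling, 67.0% with at least 500 counts and 68.9% with a pseudocount of 5. A 4-fold threshold gave 345 higher and 107 lower genes (76.3% higher), total-count scaling at 4-fold gave 284 and 142 (66.7%), and at least 500 counts at 4-fold gave 290 and 71 (80.3%). Median-of-ratios scaling, no count minimum, a pseudocount of 0.1 and removal of the most abundant genes before scaling kept the share between 62.7% and 64.4%. Over 7 alternatives the log2 ratio ranged from 5.93 to 9.26 for CJ2186, from 5.72 to 7.82 for CJ3642, from -9.36 to -8.33 for CJ2400 and from -7.86 to -7.33 for CJ5798. Among these alternatives, the changed count minimums cannot alter the ratio of a single gene. Alternatives for the gene list medians were not run, since no list could be matched. No replicate could be left out. No paired analysis was possible because each sugar had 1 library. Depth limits the folds of genes with few counts in 1 library, such as CJ2186 with 7 counts in glucose (366-fold to 1876-fold), and variation between cultures was not measured.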

Other observations

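Tests of scaling, of a single culture per sugar, of chance order of the IDs and of low counts behind the 4-fold excess were chosen after the results they bear on were seen. Those of shared reads, spill-over, length bias and low counts of short genes were set out before. The bound for length bias was replaced after the data were seen. Genes with neighbouring IDs differed between the sugars in a weakly related way. The log2 ratios of genes with consecutive IDs had a Pearson correlation of 0.115 and a Spearman correlation of 0.118 across 5507 pairs. At an ID distance of 2 the Pearson correlation was 0.018, and at a distance of 10 it was 0.0024. Of the 345 genes at least 4-fold higher in xylose, 59 had a consecutive ID of the same kind, against a median of 40 and a central 95% range of 25 to 56 in 10000 shuffled orders. Of the 107 genes at least 4-fold lower, 16 had one, against a median of 4 and a range of 0 to 10. The highest values among the shuffled orders were 77 for the higher and 16 for the lower genes, so shuffling did reach both numbers. The longest run of consecutive IDs at least 4-fold higher held 4 genes, and run lengths were not compared with shuffled orders.

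The files do not say that IDs follow the order of genes on chromosomes, and the correlation that falls off within a distance of 2 is consistent with such an order as a hypothesis. Chance order is argued against, since the correlation of 0.115 lay above the highest of 10000 shuffled orders, 0.0483. Reads shared between similar tandem copies do not account for the whole, since pairs whose coding lengths differed by more than 20% still had a correlation of 0.100 (4361 pairs, upper end of the central 95% of shuffled orders 0.0290). Reads spilling over from a neighbour more than 4-fold as abundant do not either. The 2790 pairs with at least 500 counts per gene and mean CPM within 4-fold had a correlation of 0.160 (upper end of that range 0.0373). Shared regulation of neighbouring genes, overlapping transcripts of similar abundance, spill-over within 4-fold abundance and copies of unequal length stay open, and none was tested.

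The excess of higher over lower genes had parts of unlike standing. At 2-fold it may come from the scaling alone, since the share of higher genes was 44.8% with total-count scaling. At 4-fold it remained under total-count scaling, with 66.7% higher (95% interval over genes 62.0% to 71.1%). The true scaling is not known, so a larger shift in the same direction is not excluded by this. Low counts do not explain the 4-fold excess, with 80.3% higher among genes with at least 500 counts (75.9% to 84.3%). Whether the sugar or a difference between single cultures underlies it cannot be told apart, because there was 1 library per sugar. That more genes are induced than repressed at least 4-fold in xylose is a hypothesis that needs replicate cultures. An excess of higher genes was not seen at 32-fold, with 6 higher and 10 lower genes, and 4 and 13 with total-count scaling. These genes are too few to tell whether the excess ends there, and their split changed with the pseudocount.

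The larger share of short genes at least 4-fold higher in xylose was not a matter of low counts, but it was seen at the 4-fold threshold and not at 2-fold, where the shares were 16.8% of the shortest and 16.5% of the longest quartile. With at least 500 counts the share was 8.99% of the shortest quartile (103 of 1146 genes, 7.40% to 10.8%) and 5.13% of the longest (65 of 1268 genes, 3.98% to 6.49%). The medians do not show a uniform length-dependent shift between the libraries large enough to give this difference. The median log2 ratio of the shortest quartile minus that of the longest was -0.034. A shift of 0.38, in the other direction, would give the longest quartile the share of the shortest. This size was worked out from these data, and the bound of 0.5 set before was too wide. A true difference between the quartiles could offset such a shift, so it cannot be told whether one contributes. Single genes of the shortest quartile spread with an SD of 1.16, which is not the error of a median. A length-dependent bias that is not a uniform shift of the quartile stays open as well. What the short genes encode is not known from the files, and no biological explanation was tested.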
